A study of Mus musculus with 2 samples.

How the data were processed

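Total RNA from 1 control Atp4bCre stomach and 1 Atp4bCre; MIST1-LSL stomach was amplified, biotin-labelled and hybridised to Affymetrix arrays, per the labels' protocols. Amplification before labelling can change the relative level of transcripts. Per the submitters' processing notes the data were processed with RMA and Partek. RMA corrects background, quantile-normalizes arrays and summarises the probes of each probe set on the log2 scale. Versions, settings, the genome build and the annotation are not given in the sources used here. The deposited series table holds log2 levels for 41345 probe sets. A workbook by the authors holds the same log2 levels, which differ by at most 0.005 because 1 column of the series table was rounded. It also gives the linear intensity (2 to the power of the deposited log2 level), the ratio of MIST1-LSL to control intensity computed by the authors, and the probes per probe set. Its other sheets are gene ontology enrichments by the authors, with a p-value, a score equal to the negative natural log of the p-value, and the percent of each term's genes in the list tested. Scanner intensity files and detection calls were not analysed here, so no call of presence could be made.

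Gene names came from the workbook's assignment column, which is cut off after its first transcripts, so further genes matched by a probe set cannot be seen. Of the probe sets, 32471 carried a gene and 8874 did not. Names were updated through the reference table of assembly GRCm38.p6: 21749 probe sets matched by transcript accession, 1994 by gene identifier and 4580 by symbol, while 4148 kept the name in the file. In the workbook's symbol column 27 names had been turned into numbers by the spreadsheet, and the assignment column was used for these as well. No coordinates are given because the build used for the arrays is not stated. Of 41 fixed gene lists, members without a named probe set were left out.

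For each gene the probe set with the highest mean of the 2 arrays was used. Genes were kept when the higher of their levels was at or above 4.62, the median of all probe-set values, which left 17387 genes. No rescaling was applied. The size rule was a log2 difference of at least 1, a 2-fold difference. With 1 array per genotype there was no test between genotypes. For each list the median log2 difference was compared with 10000 random lists of the same size matched on mean level in 10 bins, as a description of these 2 arrays. A list was called apart when its median lay outside the middle 95% of random lists. Intervals of list medians are 95% intervals from 2000 resamplings of the list's genes and do not cover variation between mice. Genes named in the text were Bhlha15, the 12 genes furthest above and furthest below control, and up to 4 members of each list with the largest difference, with more allowed for parietal, chief and MIST1-linked genes. The samples, comparisons, lists, naming rule and alternative settings were fixed before the data were examined. A few genes outside the rule were named after their values were seen: Tff2, Cd44, Tff1, Gkn1, Gkn2, Ghrl, Sst, Mki67, Xbp1, Irf1, Kit, Clps, Ptf1a, Fabp2, Sprr1a, Mpo, Cxcr2, Ly6g, Elane, Csf3r, Ifi204, Ifi205, Amy2b and Sycn. The closing section also names genes outside the rule, among them Ins1, Ins2, Xist, Ddx3y, Eif2s3y, Uty and Kdm5d from lists written for it.

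The procedure was tested on simulated data with 200 changed genes among 17469, with noise set from the spread of these arrays. It recovered all genes changed by 2 or 3 log2 units and 93.9% to 100.0% of those changed by 1.5. Among unchanged genes, 0.162% passed the size rule. Of 100 unchanged lists 4 were called apart, and of 100 lists shifted by 0.5 log2 units 100 were. The simulated noise was normal and independent between probe sets, so it held no co-expression within lists and no variation between mice. These shares are therefore not rates of false calls on the real arrays. Alternatives were quantile normalization, median centring, loess (span 0.3), the workbook values, no floor, a floor at the 75th percentile, averaging probe sets, the probe set with the largest difference, and 1.5-fold and 3-fold size rules. Restricting to probe sets of at least 10 probes, and leaving out acinar or immunoglobulin genes, were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.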

Results

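RNA from the stomachs of 2 mice, both 12 weeks old, was profiled on Affymetrix arrays, with 1 array per genotype. The control mouse carried Atp4bCre, which drives Cre recombinase from the promoter of the parietal cell proton pump. The other mouse carried Atp4bCre together with a MIST1-LSL allele, in which MIST1 is expressed after Cre removes a stop cassette. MIST1, encoded by Bhlha15, is a transcription factor of professional secretory cells such as gastric chief cells and pancreatic acinar cells. The comparison asks which genes differ in level when MIST1 is forced on in parietal cells, the acid-secreting cells of the stomach. The sample labels name the corpus, whereas the design text of the series says that whole stomachs were taken. Transcripts of the squamous forestomach were abundant on both arrays (Sprr1a at 11.94 on the control array and 11.85 on the MIST1-LSL array, on the log2 scale), as was the small intestinal transcript Fabp2 (10.10 and 10.00).

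The 41345 probe sets of the 2 arrays had nearly the same distribution of levels, with medians of 4.64 for control and 4.60 for MIST1-LSL on the log2 scale. Across probe sets, which are not independent replicates, the arrays correlated at r = 0.972. With 1 array per genotype no difference below has a replicate check, and no p-value across genes was computed. The number of arrays limits the precision. Log2 differences are MIST1-LSL minus control throughout. Probe sets of the same gene differed from each other with an SD of 0.203 over 478 genes, which measures probe behaviour within these arrays and not variation between mice.

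Bhlha15 was at nearly the same level on both arrays. Its single probe set, of 19 probes, read 5.26 in control and 5.30 in MIST1-LSL, a log2 difference of 0.04. Which part of the Bhlha15 transcript these probes cover is not given, so a transgene lacking that part would go unseen and the value checks the label only in part. Among genes linked to MIST1 in earlier work, Elapor1, an endosomal and lysosomal membrane protein, was 0.99 higher (7.06 and 8.05). Rab26, a GTPase of secretory granules, was 0.70 higher (4.38 and 5.08). Rab3d, another granule GTPase, was 0.23 higher (5.89 and 6.12) and Ccpg1, an ER-phagy receptor, was also 0.23 higher. Gjb1, Cdkn1a and Arfgef3 differed by -0.18, -0.11 and -0.11. Of the 8 members above the floor, 5 were above 0 and none reached a 2-fold difference. Their median was 0.14, at the 93.1 percentile of random lists matched on expression. The pancreatic acinar list, whose cells normally express several of these genes, was 4.34 higher on the same array.

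Of 17387 genes above the expression floor, 169 were at least 2-fold higher and 81 at least 2-fold lower in the MIST1-LSL stomach, together 1.44% of genes. The middle 95% of genes lay between -0.64 and 0.68. Of the 12 genes furthest above control, 9 were on the pancreatic acinar list, and the others were Zg16, 2210010C04Rik and S100g. Those furthest below it included a B cell chemokine, immunoglobulin genes, the fatty acid transporter gene Cd36, the adipsin gene Cfd and the parietal cell anion transporter Slc26a7. Also among the 12 genes furthest below control, Efcab1 was 6.64-fold lower, the predicted gene Gm15543 5.29-fold, the receptor gene Gpr155 4.85-fold and the fucosyltransferase gene Fut9 4.78-fold. Many fold differences rest on 1 level below the floor of 4.62, where signal was not shown to exceed background, so their exact size and rank are uncertain. This held for the control level of 7 of the 12 genes furthest above control and for the MIST1-LSL level of 6 of the 12 furthest below it, and for 67 of the 169 higher and 43 of the 81 lower genes. All 7 of the 2-fold genes with several probe sets above the floor had them in the same direction.

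**Figure D1:**
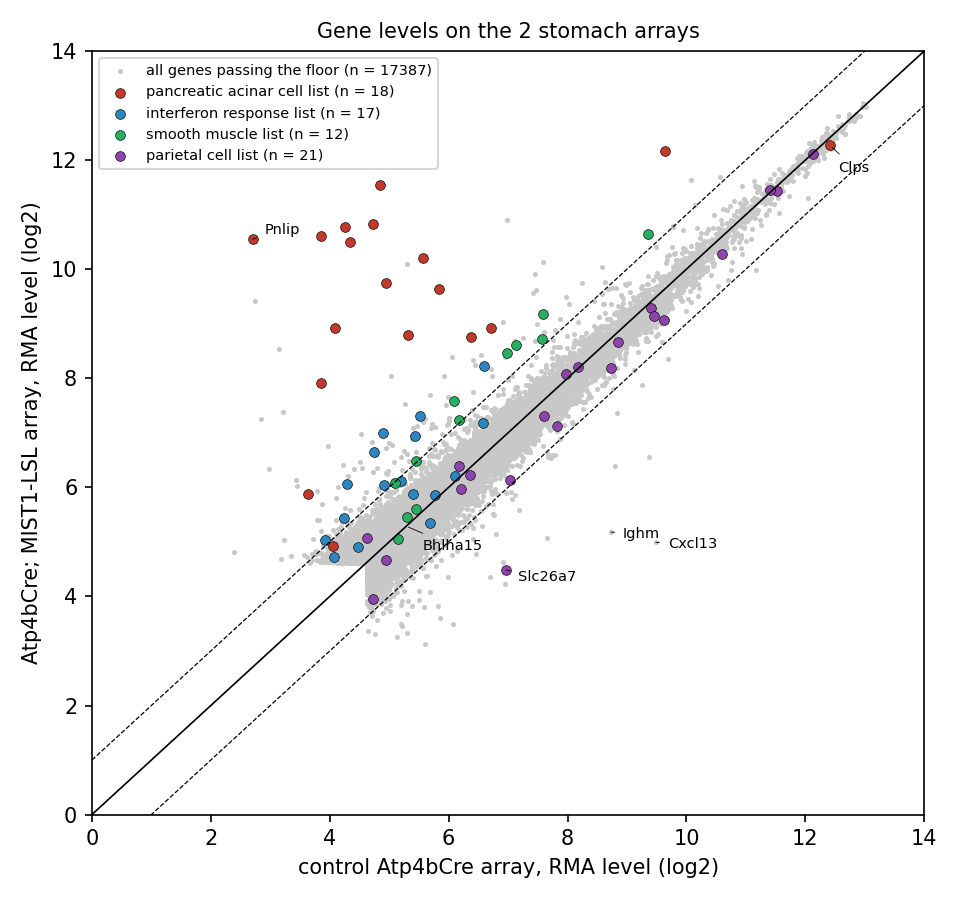
Each point is a gene above the floor, with its RMA level on the control array (x axis, log2) and on the MIST1-LSL array (y axis, log2), 1 array each; the solid line marks equal levels, the dashed lines a log2 difference of 1, and colours mark 4 gene lists. Pnlip stands 7.85 above the line of equal levels and Cxcl13 4.50 below it (-4.50), while Bhlha15 and Clps lie close to it.

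Pancreatic acinar genes had the largest differences on the higher side, and 16 of the 169 higher genes were on the fixed acinar list, which does not hold every acinar gene (Amy2b, an amylase, was 4.42 higher and Sycn, a zymogen granule protein, 3.92 higher outside it). Pnlip, pancreatic lipase, read 2.70 in control and 10.55 in MIST1-LSL, a 230.3-fold difference against a control level below the floor. Prss2, a trypsinogen, was 107.7-fold higher, the secreted protein Reg1 104.5-fold, the zymogen granule protein Zg16 102.2-fold and Cpb1, carboxypeptidase B, 91.3-fold, and of these 4 only Reg1 was above the floor on the control array (4.84). Ctrl and Ctrb1, chymotrypsin family proteases, were 71.3-fold and 68.6-fold higher. The remaining 5 of the 12 genes furthest above control were the RIKEN gene 2210010C04Rik at 42.0-fold, Cela3b, an elastase, at 28.6-fold, Cpa1, carboxypeptidase A1, at 28.1-fold, S100g, a calcium-binding protein, at 27.7-fold and the trypsin inhibitor Spink1 at 24.8-fold. Trypsinogens, amylases and chymotrypsins belong to families of near-identical copies, so the share of each copy is uncertain. Of the 18 acinar genes on the list, 16 were at least 2-fold higher. The exceptions were Clps, pancreatic colipase, which was high on both arrays (12.41 and 12.28), and Ptf1a, an acinar transcription factor, which differed by 0.88 at a low level (4.05 and 4.93). The highest level of any probe set was 13.38 on the control array and 13.37 on the MIST1-LSL array, so Clps had little room to rise. The list median of 4.34 (95% resampling interval over genes 2.46 to 6.13) exceeded that of all 10000 random lists, whose middle 95% ran from -0.17 to 0.12.

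Parietal cell genes were modestly lower as a group. The list median was -0.24 (resampling interval -0.33 to -0.10), at the 0.09 percentile of random lists, with 16 of 21 genes below 0 and 1 at least 2-fold lower. Slc26a7, a chloride and bicarbonate transporter, read 6.97 in control and 4.48 in MIST1-LSL, which is below the floor, 5.62-fold lower. Ppargc1a, a coactivator of mitochondrial biogenesis, differed by -0.90, the water channel Aqp4 by -0.77, the potassium channel Kcnj15 by -0.71, and Slc26a9 and Kcnj16 by -0.55 each. The proton pump subunits Atp4a (11.53 and 11.43) and Atp4b (12.13 and 12.11) differed by -0.10 and -0.02. Kcne2 and Kcnq1, which form the apical potassium channel of the pump, differed by 0.10 and 0.22, and carbonic anhydrase Car2 by 0.05.

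Among the other gastric epithelial lists, the chief, mucous neck, surface pit and antral medians lay within the middle 95% of random lists. The enteroendocrine and forestomach medians lay above it. Among chief cell genes, the zymogens Pga5 and Pgc differed by -0.71 and -0.19, Cblif (gastric intrinsic factor) by -0.22 and the chitinase Chia1 by -0.12, while Rnase1, a ribonuclease also made by the pancreas, was 2.15 higher. The chief cell median of -0.12 lay at the 18.0 percentile. The mucous neck and metaplasia list had a median of 0.03 at the 74.0 percentile, with the metaplasia marker Wfdc2 1.06 higher and the neck cell mucin Muc6 at -0.64. Its member Tff2 differed by -0.06 and Cd44 by -0.03. Surface pit cell genes had a median of -0.08 at the 21.4 percentile. The pit mucin Muc5ac differed by -0.74, whereas Tff1, Gkn1 and Gkn2 each differed by less than the SD between probe sets of 1 gene. Enteroendocrine genes had a median of 0.29 (resampling interval 0.05 to 0.48) at the 99.8 percentile, with the granule proteins Scg2 and Chgb 1.39 and 1.19 higher, while the hormone genes Ghrl and Sst differed by 0.05 and 0.11. The median came to 0.14 at the 97.4 percentile without an expression floor and to 0.17 at the 95.9 percentile with the floor at the 75th percentile, both within the middle 95% of random lists. Forestomach squamous genes had a median of 0.20 (resampling interval -0.01 to 0.23) at the 99.9 percentile with no member at a 2-fold difference, and Krt15, a basal keratin, was 0.90 higher. Antral and pyloric genes had a median of -0.07, with Gast (gastrin) at -0.25 and Bpifb1, a secreted epithelial protein, at 1.51. Cell cycle genes had a median of -0.01 at the 59.2 percentile, with Mki67 at -0.15 and Mcm5 at -0.91.

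The smooth muscle and nerve lists had higher medians in the MIST1-LSL stomach. The smooth muscle median was 1.11 (resampling interval 0.57 to 1.48), above all random lists, and 8 of 12 genes were at least 2-fold higher. Acta2, smooth muscle actin, was 2.99-fold higher, Myl9 2.81-fold, and Tagln and Cnn1 2.80-fold each. Genes of nerves and interstitial cells of Cajal had a median of 0.45 (resampling interval 0.08 to 1.05), above all random lists, with the neuropeptides Gal and Vip 1.97 and 1.65 higher, and the synaptic protein Snap25 1.43 higher. Of the 12 genes of this list above the floor, 3 were at least 2-fold higher and 3 were below 0. Among those below 0, Kit, the marker of interstitial cells of Cajal and mast cells, differed by -0.38. Endothelial genes had a median of -0.06 at the 44.6 percentile. Fibroblast and matrix genes had a median of -0.20 (resampling interval -0.46 to 0.04) at the 2.08 percentile, with Postn (periostin) at -1.14 and Dcn (decorin) at -0.83, and the list lay inside the middle 95% of random lists, at the 3.97 percentile, with the floor at the 75th percentile. Adipocyte genes were lower, with a median of -0.72 (resampling interval -1.39 to -0.34) that was below all random lists. Cfd, adipsin, was 5.03-fold lower and Lpl, lipoprotein lipase, 2.62-fold lower, and Fabp4 and Retn differed by -0.89 and -0.88. Outside the list, the fatty acid transporter Cd36 was 7.01-fold lower (9.37 and 6.56).

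Immune genes differed in opposite directions by lineage. Cxcl13, the chemokine that draws B cells into lymphoid follicles, lay furthest below control of all genes above the floor. It read 9.49 in control and 4.99 in MIST1-LSL, a 22.6-fold difference. Ighm, the heavy chain constant region of immunoglobulin M, was 11.7-fold lower, a value that came to -1.94 on the log2 scale when its probe sets were averaged. Kappa chain segments Igkv4-55 and Igkv8-16 were 5.99-fold and 5.98-fold lower, and a further kappa segment was 5.59-fold lower. Such segments resemble one another closely, so their individual levels are uncertain. The B cell and plasma cell median was -0.54 (resampling interval -0.74 to -0.27) at the 0.05 percentile, with 6 of 7 genes below 0, and MHC class II genes had a median of -0.37 (resampling interval -0.44 to 0.10) at the 0.25 percentile (H2-Ab1 -0.45, H2-Eb1 -0.42, Cd74 -0.41). Macrophage and dendritic cell genes had a median of -0.16 at the 11.6 percentile, with Lyz2 (lysozyme) at -1.19, and with the floor at the 75th percentile the median came to -0.39 at the 1.17 percentile, outside the middle 95% of random lists. T cell and NK cell genes had a median of 0.01 (resampling interval -0.19 to 0.85) at the 60.7 percentile over the 6 of 14 members above the floor, and Gzmb (granzyme B) was 2.54-fold higher.

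The interferon response list was higher, with a median of 1.12 (resampling interval 0.47 to 1.64) that was above all random lists, and 9 of 17 genes at least 2-fold higher. Ifit1 was 4.30-fold higher, Oas2 3.73-fold, Rtp4 3.44-fold and Ifi44 3.42-fold. The interferon regulatory factor Irf1 differed by -0.35, and outside the list the interferon-activated genes Ifi205 and Ifi204 were 3.37-fold and 2.96-fold lower. Neutrophil and mast cell genes had a median of 0.99 (resampling interval 0.34 to 1.44), above all random lists, with 6 of 12 genes at least 2-fold higher. The mast cell genes Fcer1a and Mcpt4 were 1.69 and 1.37 higher. The alarmins S100a8 and S100a9 were 1.77 and 1.51 higher, but other neutrophil members did not follow: Mpo and Cxcr2 differed by -0.37 and 0.18, and Ly6g, Elane and Csf3r were below the floor on both arrays.

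Genes of the secretory apparatus differed little. ER chaperones had a median of -0.18 (resampling interval -0.24 to -0.08) at the 0.65 percentile, with 18 of 20 genes below 0 and none at a 2-fold difference. Dnajb11, Hsp90b1, Canx and Calr differed by -0.39, -0.38, -0.37 and -0.28. The ER stress transcription factor gene Xbp1 read 7.64 on both arrays. Medians of ER-associated degradation, ER translocation and glycosylation, COPI and COPII transport and regulated exocytosis genes were -0.10, -0.12, -0.04 and -0.07, at percentiles 18.0, 4.67, 38.0 and 28.8. Tmed6, a cargo receptor of the early secretory pathway, was the only member of these 4 lists at a 2-fold difference, 1.24 higher (9.35 and 10.59). ATF4 and CHOP stress genes had a median of 0.05, with Slc7a11, a cystine transporter, 1.61 higher and Atf3 0.94 higher.

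Metabolic and organelle lists also stayed close to 0. Respiratory chain genes had a median of 0.06 at the 97.4 percentile, and lay outside the middle 95% of random lists under 5 of 9 alternative settings. Medians were -0.01 for the TCA cycle, -0.14 for fatty acid oxidation, -0.02 for glycolysis, 0.10 for cholesterol synthesis, -0.09 for the lysosome and 0.03 for the vacuolar ATPase, at percentiles 58.1, 5.91, 53.6, 95.7, 16.9 and 78.3. Oxidative stress and immediate early genes both had medians of 0.03, at percentiles 73.7 and 72.2. Skeletal muscle, red blood cell and small intestinal epithelium lists had medians of -0.05, 0.13 and -0.07, at percentiles 46.2, 75.7 and 29.8. The control lists of ribosomal proteins and housekeeping genes had medians of -0.0047 and -0.02, at percentiles 66.1 and 54.8. Of the 41 lists, 13 lay outside the middle 95% of random lists. Lists of unrelated genes would place 2.05 there on average. Genes of a list that vary together between mice fall outside more often, so 2.05 is no baseline for these lists. Lists sharing genes or cell types also do not count separately.

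**Figure D2:**
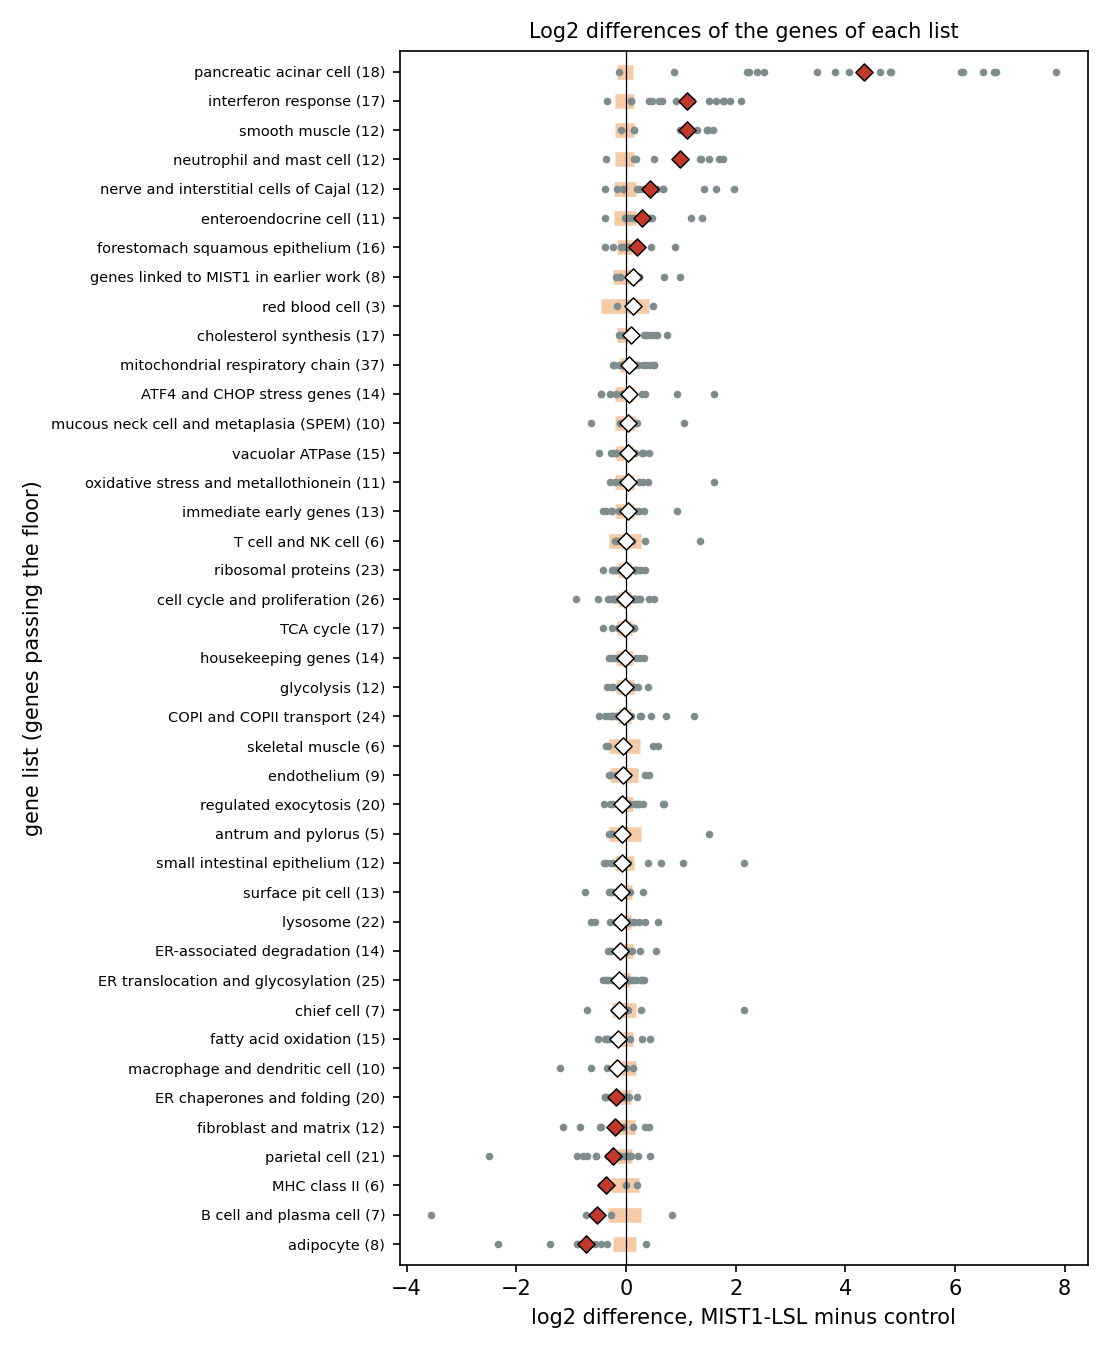
Each row is a gene list with the number of its genes above the floor, the x axis is the log2 difference (MIST1-LSL minus control), grey points are genes, diamonds are list medians, and orange bars span the middle 95% of medians of 10000 random lists matched on expression. Filled diamonds mark the 13 lists outside that span, from the acinar list at 4.34 to the adipocyte list at -0.72.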

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

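The unnamed probe sets below were picked after their values were seen, while the tests of the 3 patterns that follow were written down before the medians they measure but after the genes with the largest differences, Cxcl13 among them, had been seen. The condition that fewer than 5 islet genes above the floor leave that test open was added after the values were seen. So were both comparisons with genes at the same level, which replace tests of normalization by rescaling. Rescaling moved these arrays too little to decide, and the same-level corrections were also small. Probe sets without a gene name entered no comparison of genes or lists above, though they counted in the array medians, the correlation and the floor. Of 1760 such probe sets with at least 10 probes, 30 were at least 2-fold higher and 10 at least 2-fold lower in MIST1-LSL. Signals far above the control array were seen on 4 of them: probe set 17505769 was 7.70 higher on the log2 scale (4.02 and 11.72), 17548538 was 6.44 higher (5.05 and 11.49), 17483997 was 4.55 higher (3.87 and 8.42) and 17549060 was 3.70 higher (3.26 and 6.96). These probe sets were picked for a log2 difference of at least 3 and a MIST1-LSL level above the floor. Their sizes therefore do not tell which transcripts they measure, and this is not given.

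The acinar genes were 4.34 higher in the median. Other genes in the 10 level bins had medians from -0.0706 to -0.0154, so a trend shared by genes of a level was far smaller. Taking these medians off left 4.37 (2.48 to 6.16). That was bound to change little and is no independent test, because the random lists were already matched on level. Pancreatic tissue attached to the MIST1-LSL stomach may be the source, but the test through islet genes stayed open: their median was -0.28 with only 3 of 10 members above the floor, and Ins1 (3.66 and 3.57) and Ins2 (3.97 and 3.85) were below the floor on both arrays. That meets the value set in advance against pancreatic tissue, yet genes near the floor cannot exclude exocrine tissue free of islets. Small intestinal tissue also stayed open, with a list median of -0.0735 (-0.26 to 0.52) over members that went both ways, and induction by MIST1 itself is untested, because genotype and dissection cannot be told apart with 1 mouse each. The array did not show MIST1 itself raised (Bhlha15 5.26 and 5.30), though whether its probe set covers the transgene is not given. Pancreatic acinar cells express MIST1 too, so this value does not tell attached pancreatic tissue and induction apart.

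Parietal genes were lower by a median of -0.24. After the median of other genes at the same level was taken off it was -0.22 (-0.30 to -0.07). Those level medians ran from -0.0702 to -0.0154, so a trend shared by genes of a level was smaller than the parietal difference. As for the acinar genes, taking the level medians off was bound to change little and is no independent test. Dilution by other tissue may contribute: pit, neck and chief cell genes together had a median of -0.05, and the parietal median lay -0.19 from theirs (-0.34 to 0.0028), so the interval reached just past 0 and the question stays open. Several pit and neck genes, such as Gkn1 (13.02 and 12.98) and Tff2 (12.84 and 12.78), read near the highest control level of 13.38. Whether differences are muted at such levels was not tested. An effect of MIST1 on parietal cells is the biological explanation the design names, and 1 mouse per genotype does not test it.

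B cell genes were lower by a median of -0.54, and 20 of 78 immunoglobulin genes and gene segments were at least 2-fold lower, with a median over the 78 of -0.35. Fewer lymphoid cells in the MIST1-LSL sample could account for this, but T cell genes had a median of 0.0075 (-0.19 to 0.85) over only 6 of 14 members above the floor, while the follicle list (with Cxcl13) had a median of -0.40 (-4.50 to 0.58), so with few members and wide intervals the tests settled nothing. Whether the difference belongs to the genotype, the piece of tissue or the mouse stays open.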

How the results depend on the processing

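No paired analysis was possible because each genotype had 1 array, and for the same reason no replicate could be left out. Genes at least 2-fold higher numbered 169 and genes lower 81. With no floor the counts were 357 and 198, out of 30947 genes. With the floor at the 75th percentile they were 127 and 42. A 1.5-fold rule gave 608 and 583, and a 3-fold rule 67 and 24. Under quantile normalization, median centring, loess, the workbook values, averaging and the largest-difference probe set, the higher count ran from 168 to 179 and the lower from 73 to 82. All 169 higher genes and 73 to 75 of the 81 lower genes stayed in the counts under the 3 rescalings. After the data were seen, probe sets of at least 10 probes gave 142 and 60, leaving out the acinar list gave 153 higher and leaving out immunoglobulin genes gave 61 lower. The 153 still hold acinar genes outside the list, Amy2b and Sycn among them. Bhlha15 moved by less than the SD between probe sets. Of 363 list medians under the alternatives, 361 stayed within the list's resampling interval. The others were red blood cell genes without a floor (-0.18, against 0.13) and respiratory chain genes under loess (0.093, against 0.06), and the cause was not tested. No list called apart changed sign, and 11 of 13 stayed apart under every alternative run. The exceptions were enteroendocrine genes without a floor or with the higher floor, and fibroblast genes with the higher floor. Low signal and few probes limit single genes: differences had an SD of 0.717 for probe sets under 10 probes and 0.378 for larger ones.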

Other observations

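The intestinal and secretory genes named in this paragraph were chosen after their values were seen, and they were not tested as a group. Of 18 Paneth cell defensin genes (Defa) above the floor, 5 were at least 2-fold higher in MIST1-LSL and none lower, with Defa17 3.02 higher and Defa24 2.15 higher. These are near-identical copies, so their single levels are uncertain. Regenerating family genes Reg3g and Reg3b, antimicrobial lectins, were 1.82 and 1.56 higher, and the enterocyte hormones Guca2a and Guca2b 1.45 and 1.27 higher. Enterocyte genes went both ways. On the small intestinal list, which also holds Defa24, 5 of 12 members above the floor were above 0 and 7 below. Alpi, Fabp1 and Cdx2 differed by 1.04, 0.63 and 0.41. Apob, Lyz1, Apoa1, Vil1 and Fabp2 differed by -0.40, -0.36, -0.27, -0.24 and -0.10. Outside it S100g, Cdhr5, Akp3 and Slc5a1 were 4.79, 1.82, 1.58 and 1.08 higher.

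Both mice had the same sex-linked pattern: Xist was high on both arrays (10.75 and 9.99), and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were below the floor on both.

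The gene ontology sheet that the authors named for the top of the MIST1-LSL list may hold genes that were lower in MIST1-LSL, a hypothesis raised by its terms and then tested. In the authors' deposited table, its B cell receptor signaling term had 43.8% of genes in the list (p = 0.00156), whereas in the sheet without a descriptive name 2'-5'-oligoadenylate synthetase activity had 90.9% (p = 1.1802e-06) and serine-type endopeptidase activity 33.0% (p = 4.84018e-05). These terms were picked for their direction. In the authors' deposited table, terms with smaller p-values do not bear on it as plainly: signal transduction had 22.6% (p = 1.40145e-08) in the named sheet and 21.6% in the other, and olfactory receptor activity 21.9% in the named sheet and 32.9% (p = 6.09043e-23) in the other. Across 240 terms with at least 20 assigned genes, the percent in the named sheet correlated at rho = 0.557 with the share of term genes lower by at least 0.32 on the log2 scale and at -0.07 with the share higher by as much. For the other sheet the values were -0.06 and 0.590. Terms overlap and are not independent, and the assignments used are cut off after the first terms, so these correlations describe the sheets and carry no p-value.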
